A study of Mus musculus with 15 samples.

How the data were processed

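The samples were murine bone marrow-derived macrophages, which are macrophages grown in culture from bone marrow precursors, here of C57BL/6 mice at day 7 of differentiation. Cells were left untreated or given 10 ng/ml lipopolysaccharide (LPS), a bacterial cell wall component that activates macrophages, for 30 min, 1 h, 2 h or 4 h. Chromatin-associated RNA, the fraction that stays with chromatin when nuclei are fractionated and that is rich in RNA still being transcribed, was sequenced from 3 libraries in each of the 5 groups, 15 in all. Groups and replicate numbers were taken from the labels.

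Per the submitters' processing notes, transcripts were quantified with kallisto 0.44.0, which assigns reads to annotated transcripts without a genome alignment. The transcript annotation, the genome build and the fragment length setting are not given in the sources used here. The authors deposited, for each library, the estimated count and the TPM (an abundance scaled for length and depth that sums to the same total in every library) of 113193 transcripts, named by Ensembl transcript identifiers. Estimated counts were not whole numbers, because kallisto divides reads that fit several isoforms among them, and they were rounded to whole numbers before testing. The deposited files hold no measure of that assignment uncertainty, so the errors given here leave it out. Effective lengths were identical in all 15 libraries and lay 299 nt below the length for long transcripts. No transcript shorter than 281 nt, of which there were 3247, had a count in any library. Libraries were unstranded per the labels, so that reads of overlapping transcripts on opposite strands cannot be told apart. An index of spliced transcripts counts intronic reads only where an annotated transcript includes them, and the share of reads outside annotated transcripts is not given in the sources used here.

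The planned unit of testing was the gene, with the counts of its transcripts summed. The reference table used here has 49997 genes and no Ensembl identifiers, and 0 of the transcript identifiers matched it, so the fallback written before the data were examined was followed and the same test was run on transcripts. Counts of changed transcripts are therefore not counts of genes, and isoforms of one gene are not independent. Tests of gene lists, shares of RNA classes defined by gene names, gene sums and a count restricted to protein-coding transcripts were not run. For the same reason gene symbols are not given.

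Counts were compared with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test. All 15 libraries entered one fit with a term for each group and no other term. Library sizes were scaled with TMM factors, which ranged from 0.679 to 1.52. Transcripts with low counts were removed with the filterByExpr function (minimum count 10, minimum total 15), which left 46186, holding 99.1% to 99.6% of the estimated counts of each library. P-values were adjusted by the Benjamini-Hochberg method and a transcript was called changed at an adjusted p under 0.05. Each time was compared with untreated cells, each time with the one before it, and all 4 times together with untreated cells in one F test. Levels are given as CPM (counts scaled to a common library size) with TMM scaling. Where all libraries of a group had a count of 0, the fold is a lower bound computed against 3 counts in each library of that group. Log2 fold changes are those of the fit, and medians over sets are also given with such transcripts at their bound. Shares of counts were compared by exact permutation tests, two-sided, for which 3 libraries against 3 give no p below 0.1, and, as a test added after the results were seen, by sign changes of the differences of same-numbered libraries, for which 3 pairs give no p below 0.25. The share of a single transcript in 1 library has a 95% Wilson interval. Intervals and floors cover counting error only. Nothing in the labels says that the replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

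The rule for naming features was fixed before the data were examined. It took, among transcripts called at a time with a mean of at least 10 CPM in either group and with all 3 LPS libraries on one side of all 3 untreated libraries, the largest rises and falls by fitted log2 fold change. Its condition on gene symbols could not be applied, and without a table of names it was limited to 2 rises and 2 falls over the 4 times. Fitted values of groups at 0 depend on the prior count, so the order is not one of measured change. The most abundant transcript was named after its values were seen.

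The labels give the same replicate numbers 1 to 3 in every group. Whether they pair the libraries was decided from the deviations of log2 CPM from group means, before the fits with and without the number were compared. All 30 pairs of libraries of different groups with the same number correlated positively (r across transcripts from 0.216 to 0.483, median 0.360), and all 60 pairs with different numbers correlated negatively (-0.306 to -0.005). Deviations within a group of 3 sum to 0, so the negative values follow in part from the positive ones and are not separate evidence. Transcripts are not independent replicates in these values. Each of the 15 libraries correlated best with libraries of its own number. Because every same-number pair was over 0.1, a second fit with the number as a block is given beside the results. The labels do not say what libraries of one number share. The libraries were also checked for duplicates. Within groups the lowest chi-square per degree of freedom was 37.1 and r of log2 CPM was 0.685 to 0.781, and across the 90 pairs of different groups these were at least 17.8 and 0.550 to 0.849, so no 2 libraries agreed within sampling noise.

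The test was run on simulated counts with 200 of 46186 transcripts changed at 4 h, in 4 simulations per setting. In the version written first, with edgeR's tagwise dispersions and changes of 2-, 4- and 8-fold, the estimated changes had medians of 0.92, 1.99 and 3.01 on the log2 scale, close to the true 1, 2 and 3, but 0% of the changed transcripts were called at any of these sizes, with 0 false calls. Changes of 16- and 32-fold and another spread (trended dispersion times the quasi-likelihood variance) were added after that result was seen. With the larger changes included and tagwise dispersions, 0% were called at 2- and 4-fold, 7.5% at 8-fold, 25.6% at 16-fold and 32.5% at 32-fold, with 1 false call. With the other spread, 0%, 0.625%, 16.9%, 30% and 40.6% were called at 2-, 4-, 8-, 16- and 32-fold, with 2 false calls. The share recovered depends on how many transcripts change strongly, because the Benjamini-Hochberg threshold does. At 3 libraries per group most simulated changes were missed at 4 h at every size simulated, up to 32-fold, under each setting tried. Simulated unchanged groups gave 0 calls. So that the overlap of sets called against the same untreated libraries could still be compared, the transcripts of smallest p in each direction, as many as were called in the data, were taken from them, a step added after the results were seen. Such sets hold no real change, while called sets do, and the simulated counts held no deviation shared by a replicate number. They show how far shared controls alone can make the top ranks overlap, and not how much they gave here.

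Alternatives planned before the data were examined were DESeq2 size factors, upper-quartile factors and library size alone in place of TMM, DESeq2 1.42.0 as the tool, no filter and a stricter filter on low counts (1 CPM in 3 libraries and a total of 100), the replicate block, a fit of only the 2 groups compared, limma 3.58.1 on log2(TPM + 1) and log2(TPM + 0.1), a fold threshold of 2, and leaving out each library or each replicate number. Leaving out the most abundant transcript, and combinations of that or of the block with other scalings and with left-out libraries, were chosen after seeing the data. Length offsets were void, since effective lengths did not differ between libraries, and a filter on features under 200 nt removed nothing that was counted. A first test of the share of the most abundant transcript as the only cause of the deviations shared by a number used 24 pairs with different numbers on the same side in that share (median r -0.176). It was replaced by pairs with the same number on opposite sides, because centring lowers the former, and nothing is concluded from it. A test of transcript length restricted to 1 transcript per run of neighbouring identifiers was drafted and dropped before it was run, because identifiers do not show which gene a transcript belongs to. Figures were drawn with matplotlib 3.10.9.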

Results

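Chromatin-associated RNA was profiled in murine bone marrow-derived macrophages before and after stimulation with 10 ng/ml LPS, in a series on nucleosome remodelling at regulatory elements. Such a fraction is rich in RNA on or near its template. Its levels are meant to follow transcription more closely than those of total RNA, which was not measured in these libraries. Untreated cells and cells treated for 30 min, 1 h, 2 h and 4 h were represented by 3 libraries each. The libraries held 7537521 to 11892599 estimated counts, and 48704 to 60949 of the 113193 annotated transcripts had at least 1 count. The filter on low counts left 46186 transcripts, whose median length was 2088 nt. Features are transcripts throughout, since the identifiers in the files are not paired with gene names.

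A single transcript, ENSMUST00000217116.1 (3756 nt), singled out after its values were seen, was the most abundant over all libraries. Its share of the estimated counts ranged from 9.66% in replicate 1 at 30 min (95% Wilson interval 9.64% to 9.68%) to 41.2% in replicate 3 at 4 h (41.18% to 41.24%). Neither exact test, with or without the pairing of replicate numbers, reached a p under 0.05 at any time, which this design does not allow. The share was 21.4% ± 11.96 (SD, n = 3) in untreated cells, 26.4% ± 14.8 at 30 min, 21.9% ± 9.4 at 1 h, 17.6% ± 10.1 at 2 h and 24.3% ± 15.02 at 4 h (exact permutation tests against untreated cells, two-sided p from 0.6 to 1, where 0.1 is the smallest the design allows). The 10 most abundant transcripts of each library together held 24.6% ± 11.3 of the counts in untreated cells and 22.2% ± 9.5 to 29.5% ± 14.6 after LPS (exact p from 0.6 to 1). Paired by replicate number, both shares were higher at 4 h than in untreated cells in all 3 pairs, by 0.621, 1.77 and 6.41 percentage points for the single transcript and 2.57, 3.43 and 7.97 for the 10 (exact paired p = 0.25 for each, the smallest that 3 pairs allow). At the other times the pairs went both ways (exact paired p from 0.75 to 1). The share of the single transcript varied with the replicate number too, with a mean of 11.2% over the 5 libraries numbered 1 (9.66% to 12.5%), 26.1% over those numbered 2 (17.5% to 37.6%) and 29.6% over those numbered 3 (12.3% to 41.2%).

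**Figure D1:**
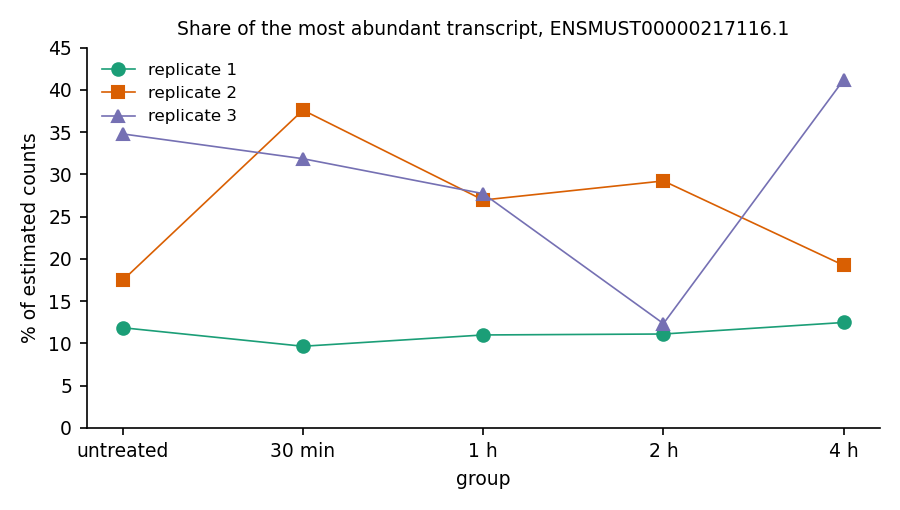
Share of the estimated counts held by the most abundant transcript (y axis, percent) in each of the 15 libraries, by group (x axis), with libraries of one replicate number joined by a line. Libraries numbered 1 lie between 9.66% and 12.5%, and the others between 12.3% and 41.2%, in no order of time.

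Both time after LPS and the replicate number set the libraries apart. The first principal component of log2 CPM held 20.6% of the variance, and 85.8% of it lay between the 5 groups, with untreated, 30 min and 1 h libraries on one side and 2 h and 4 h libraries on the other. Components 2 and 3, with 17.1% and 13% of the variance, separated replicate numbers: 91.1% and 79.4% of their variance lay between the numbers. Over all transcripts, 48.7% of the variance within groups lay between replicate numbers, where 20% would lie there without any shared deviation. Values with the replicate number as a block are therefore given beside those without.

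**Figure D2:**
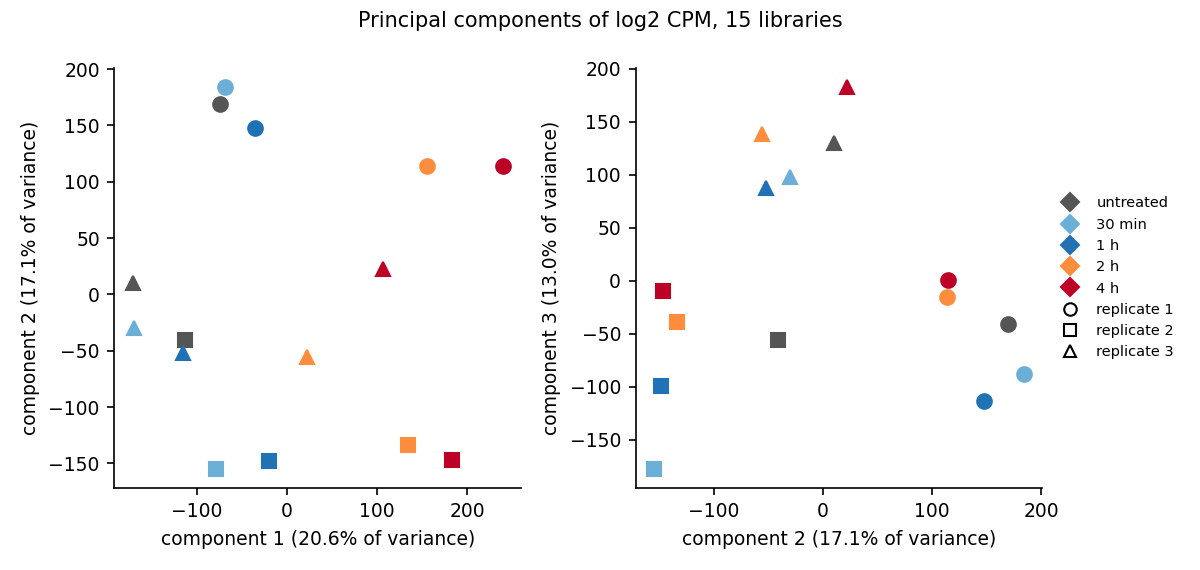
Principal components of log2 CPM for the 15 libraries, component 1 against 2 on the left and 2 against 3 on the right, in arbitrary units, with colour for the group and marker shape for the replicate number. Component 1 has 2 h and 4 h libraries on one side and the others on the opposite side (85.8% of its variance between groups), while components 2 and 3 separate the replicate numbers (91.1% and 79.4% between numbers).

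The first question is which transcripts changed at any time after LPS. Of the 46186 transcripts tested, 2942 changed in the joint test of the 4 times (edgeR quasi-likelihood F test, adjusted p under 0.05), and 7510 changed with the replicate number as a block, including 2929 of the 2942. In the single comparisons with untreated cells, 2095 transcripts were raised and 1195 lowered at 1 time or more, and 7 were raised at one time and lowered at another. The response was weighted to late times. The transcripts called at all 4 times numbered 96 among those raised and 0 among those lowered. Leaving out untreated replicate 2 or 4 h replicate 1 reduced the joint count to 1890 and 1689. Without all libraries numbered 1, 2 or 3, which left 2 per group, it was 0, 4 and 201. DESeq2 called 8404.

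At 30 min most calls were upward. Called changes are selected to be large, here and at the later times, so their size does not describe the whole response. In simulated unchanged groups the 162 transcripts of smallest p among those estimated higher had median log2 fold changes of 4.41 and 4.56 under the 2 spreads. The test called 162 transcripts raised and 8 lowered, and all 162 rose at least 4-fold, 87 of them at least 16-fold, with a median log2 fold change of 4.17 (4.13 with transcripts at 0 in untreated cells at their bound). Each of the 162 was higher and each of the 8 lower in all 3 same-numbered pairs of libraries. The calls came from these same libraries, so this agreement follows in part from the selection and is not separate evidence. Leaving the most abundant transcript aside, here and for the later times, the 162 transcripts together held 0.313% ± 0.019 of the remaining counts of untreated cells and 3.86% ± 1.70 at 30 min (SD, n = 3). At each time such shares are of transcripts called from the same libraries, so they are selected to differ. With the replicate number as a block, 423 were raised and 41 lowered, including all 170. In limma on log2(TPM + 1), which differs in tool, transform and scaling, 73.8% of the calls were raised against 95.3% here, and DESeq2 called 799 raised and 323 lowered (71.2% raised). Library size alone gave 81 calls, and edgeR with only the 2 groups in the fit gave 0, with an unadjusted p under 0.05 for 2644 transcripts. The count fell from 170 to 28, 5 and 42 without untreated replicate 1, 2 or 3 and to 74 and 113 without 30 min replicate 2 or 3, and it was 381 without 30 min replicate 1.

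At 1 h, 436 transcripts were raised and 44 lowered. Of those raised, 411 rose at least 4-fold, with a median log2 fold change of 3.56 (3.54 with groups at 0 set to their bound), and their share of the remaining counts went from 1.24% ± 0.10 to 9.19% ± 1.10. The median log2 fold change of the 44 lowered transcripts was -2.99 (-2.96 at the bound). Of the 162 raised at 30 min, 157 were also called at 1 h, where independent sets of these sizes would share 1.53, and a further 279 were called raised for the first time. These 279 had a median log2 fold change of 2.20 at 30 min (2.18 at the bound), where none passed the test. In simulated unchanged groups against the same untreated libraries, the transcripts of smallest p among those estimated higher, 162 and 436 of them, shared 72 and 75.5 on average under the 2 spreads simulated, and at most 82, so part of the 157 may come from the shared controls. With the block, 1354 were raised and 448 lowered, including 479 of the 480. DESeq2 called 1572 raised and 919 lowered (63.1% raised), library size alone 241 and a fit of only the 2 groups 146. The raised share of calls was 90.8%, but 58.0% in limma on log2(TPM + 1) and 77.5% with library size alone once the most abundant transcript was left out. The count fell from 480 to 99, 48 and 113 without untreated replicate 1, 2 or 3 and to 289, 214 and 319 without 1 h replicate 1, 2 or 3.

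By 2 h, lowered transcripts had become frequent. The test called 911 transcripts raised and 273 lowered, with median log2 fold changes of 3.17 and -2.86 (3.13 and -2.74 with groups at 0 set to their bound). Among those raised, 799 rose at least 4-fold and 276 at least 16-fold, and together they went from 2.55% ± 0.27 to 15.05% ± 2.00 of the remaining counts, while the lowered set went from 1.72% ± 0.36 to 0.222% ± 0.016. Raised calls made for the first time numbered 649, against 262 first lowered. The direct test of 2 h against 1 h called 150 raised and 45 lowered, so a first call is not by itself a change since 1 h. With the block, 2964 were raised and 1412 lowered, including 1183 of the 1184. DESeq2 called 2512 raised and 1823 lowered, library size alone 566, a fit of only the 2 groups 422 and a fit without the filter 768. The balance between the directions depended on the scaling and on the tool. In edgeR, 76.9% of the calls were raised with TMM, 72.7% with DESeq2 size factors, 65.7% with library size alone and 45.4% with library size alone once the most abundant transcript was left out. DESeq2 itself gave 57.9%, and limma on log2(TPM + 1), which differs in tool, transform and scaling, 41.4%. The count fell from 1184 to 380, 179 and 345 without untreated replicate 1, 2 or 3 and to 440 and 424 without 2 h replicate 1 or 2.

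At 4 h the response was at its widest among the times sampled. The test called 1808 transcripts raised and 1076 lowered, with median log2 fold changes of 3.07 and -3.02 (3.03 and -2.85 with groups at 0 set to their bound). Of those raised, 1531 rose at least 4-fold and 535 at least 16-fold, and of those lowered, 861 fell at least 4-fold. The raised set went from 6.92% ± 0.87 of the remaining counts in untreated cells to 32.9% ± 2.8, and the lowered set from 5.40% ± 0.83 to 0.575% ± 0.125. First calls at 4 h were 1005 raised and 882 lowered. The direct test of 4 h against 2 h called 6 raised and 18 lowered (156 and 227 with the block). A first call is a crossing of the threshold and does not by itself show a change since 2 h. With the block, 4097 were raised and 2895 lowered, including 2878 of the 2884. DESeq2 called 3577 raised and 2889 lowered (55.3% raised), and a fit of only the 2 groups called 1160. The split turned with the scaling: in edgeR, TMM gave 62.7% raised, but library size alone gave 767 raised and 2258 lowered (25.4% raised). Limma on log2(TPM + 1) and log2(TPM + 0.1), which differs in tool and transform as well, gave 23.9% and 24.3%. Library size alone put the median log2 fold change of all tested transcripts at -0.85, against -0.06 with TMM, so directions at 4 h are relative to the typical transcript. The count fell from 2884 to 1428, 1243 and 1515 without untreated replicate 1, 2 or 3 and to 1412 and 1808 without 4 h replicate 1 or 2.

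**Figure D3:**
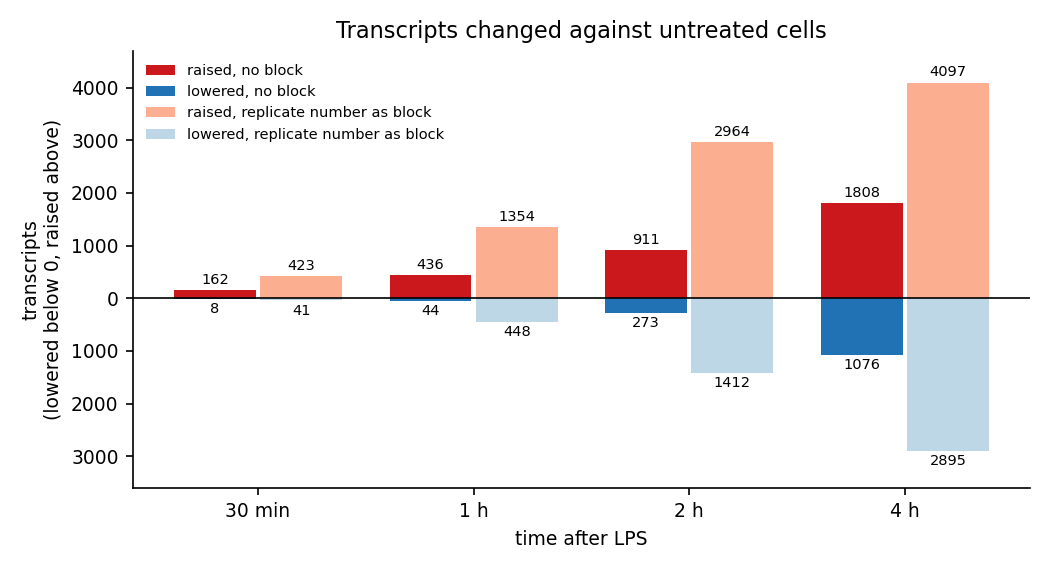
Transcripts raised (above 0) and lowered (below 0) against untreated cells at each time after LPS, by edgeR's quasi-likelihood test at an adjusted p under 0.05, without a block (dark bars) and with the replicate number as a block (light bars). Raised calls go from 162 at 30 min to 1808 at 4 h and lowered calls from 8 to 1076 without the block, with TMM scaling, and at 4 h the larger direction changes with library size alone.

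The next question is how the sets called at each time behaved at the others. Transcripts first raised at 30 min had a median log2 fold change of 4.17 at 30 min, 4.21 at 1 h, 3.33 at 2 h and 3.17 at 4 h (4.13, 4.17, 3.16 and 3.08 with groups at 0 set to their bound), and 103 and 111 of the 162 were called at 2 h and 4 h. In simulated unchanged groups the 162 transcripts of smallest p among those estimated higher at 30 min had medians of 4.41 at 30 min, 2.79 at 1 h, 2.72 at 2 h and 2.69 at 4 h with tagwise dispersions, and 4.56, 2.81, 3.01 and 2.79 with the other spread. These arise without any real change, so the medians at 2 h and 4 h do not show by themselves that the rise lasted. The 103 and 111 passed the test at 2 h and 4 h, against the same untreated libraries. The simulated groups gave 0 calls at 30 min and 4 h, as an adjusted test of unchanged groups nearly must. Their calls at 2 h were not counted. The 0 calls therefore say nothing on whether the rise lasted. Those first raised at 1 h had medians of 2.20, 3.15, 2.52 and 2.14 at the 4 times (2.18, 3.15, 2.52 and 2.10 at the bound). Those first raised at 2 h had 0.47, 1.09, 2.92 and 3.14 (0.45, 1.07, 2.91 and 3.10), and 550 of the 649 were also called at 4 h. Those first raised at 4 h had 0.33, 0.48, 1.82 and 2.71 (0.32, 0.46, 1.79 and 2.71). Among lowered sets, the 262 first lowered at 2 h had a median of -2.83 at 2 h and -2.67 at 4 h (-2.73 and -2.61 at the bound), and 178 of them were called at 4 h. The 882 first lowered at 4 h had -0.11, -0.63, -1.42 and -2.99 (-2.78 at the bound). The 8 transcripts lowered at 30 min had a median of -3.15 at 30 min with groups at 0 set to their bound and -0.40 at 2 h, where none was called. Each set is called at the time it is named for, so its value there is selected to be large, and all times share the same 3 untreated libraries, so its values at the other times are drawn the same way.

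**Figure D4:**
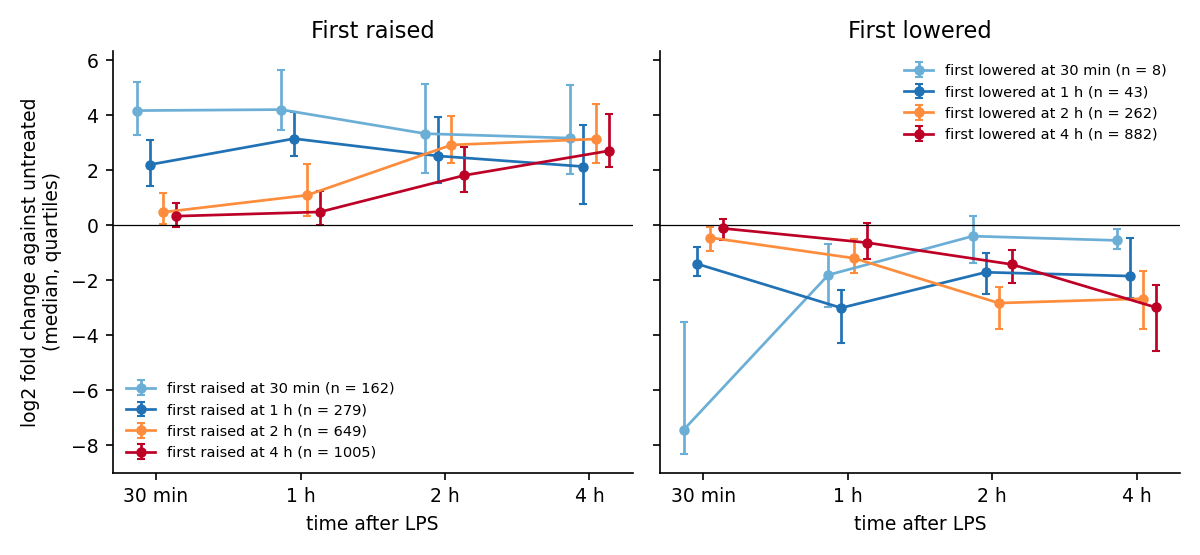
Log2 fold change against untreated cells (y axis) at each time after LPS (x axis) for transcripts grouped by the time at which they were first called raised (left) or lowered (right), as fitted medians with quartile bars. The sets first raised at 30 min and 1 h have their highest medians at 1 h (4.21 and 3.15), and those first raised at 2 h and 4 h at 4 h (3.14 and 2.71). The fitted value of the 8 transcripts lowered at 30 min includes groups at 0 and is no bound.

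Induced transcripts, defined as those past the joint test with a rise of at least 2-fold at some time, numbered 2191 and most often had their highest mean level at 4 h. The highest mean was at 4 h for 1320 (60.2%), at 2 h for 359 (16.4%), at 1 h for 360 (16.4%) and at 30 min for 152 (6.94%). The peak was read from the same libraries as the tests that follow, which are therefore not independent of that choice. Of those with a 4 h peak, 1029 differed between 4 h and 30 min by the test. Against 2 h, however, only 6 of all 46186 tested transcripts were called raised at 4 h (156 with the block). Most 4 h peaks were thus not told apart from the 2 h level. Of those with an earlier peak, the peak differed from the 4 h level for 91 of the 152 at 30 min, 198 of the 360 at 1 h and 6 of the 359 at 2 h. With the block, 352, 877, 953 and 2616 of 4798 induced transcripts had their peak at 30 min, 1 h, 2 h and 4 h, of which 235, 506 and 57 differed from 4 h and 2184 from 30 min. With library size alone, 99 had it at 30 min and 532 at 4 h.

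The sets called at 30 min and 4 h were compared. Of 162 raised at 30 min and 1808 at 4 h, 111 were in both sets, where independent sets of these sizes would share 6.34. Simulated unchanged groups against the same untreated libraries shared 0 calls, but they gave 0 calls at either time, so this measures no overlap. Among as many simulated transcripts of smallest p, 162 and 1808 of those estimated higher, 108.5 and 114.2 were shared on average under the 2 spreads, and up to 118. The 111 do not exceed these overlaps. The simulated transcripts were not called, though, and carried no deviation shared by a replicate number. How much of the 111 came from the shared controls is therefore not known, and no such overlap was simulated for the block. No transcript was lowered at both times, where 0.186 would be shared by independent sets and 2.5 and 3 were shared by the simulated ones. With the block, 285 were raised at both times (37.5 for independent sets) and 10 lowered (2.57). The 3 untreated libraries are common to both comparisons and too few to be split, so part of the excess over independent sets may come from the shared controls.

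Consecutive times were compared to see where the profile moved most. Between 30 min and 1 h no transcript was called changed by edgeR, with or without the block. An unadjusted p under 0.05 was found for 2174 transcripts, where 2309 would be found by chance, and for 4006 with the block, and DESeq2 called 222. Between 1 h and 2 h, 150 were raised and 45 lowered, with median log2 fold changes of 2.92 and -3.02 (2.88 and -3.02 with groups at 0 set to their bound), and with the block 1242 were raised and 701 lowered, including all 195. Between 2 h and 4 h, 6 were raised and 18 lowered, and with the block 156 and 227, including all 24. DESeq2 called 2373 from 1 h to 2 h and 827 from 2 h to 4 h. The count from 1 h to 2 h was 0 with library size alone and with only the 2 groups in the fit. It fell to 50, 24 and 33 without untreated replicate 1, 2 or 3, to 106 and 58 without 30 min replicate 1 or 3, to 15, 30 and 0 without 1 h replicate 1, 2 or 3, to 11 and 0 without 2 h replicate 1 or 2 and to 45 and 41 without 4 h replicate 1 or 2. The count from 2 h to 4 h was 0 with only the 2 groups in the fit. It was 13, 8 and 11 without untreated replicate 1, 2 or 3, 14 and 12 without 30 min replicate 2 or 3, 15, 14 and 2 without 1 h replicate 1, 2 or 3, 3, 0 and 9 without 2 h replicate 1, 2 or 3 and 3, 11 and 13 without 4 h replicate 1, 2 or 3. Between 30 min and 1 h, single left-out libraries gave 0 to 5 calls: 1 without untreated replicate 1, 1 and 5 without 30 min replicate 1 or 2, and 2 and 1 without 1 h replicate 1 or 2.

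The 2 highest and 2 lowest fitted fold changes among called transcripts that met the naming conditions were all found at 4 h. A fitted fold against a group at 0 depends on the prior count, so these are not shown to be the largest measured changes. ENSMUST00000198803.1 (1836 nt) had 0 counts in all 3 untreated libraries, which allows a mean of up to 0.263 CPM, and 406 ± 218 CPM at 4 h (SD, n = 3), at least 1547.5-fold higher (edgeR adjusted p = 0.0142, and 0.00965 with the block). It had 28.7 ± 49.2 CPM at 30 min, 85.5 CPM of it in replicate 2 and under 0.3 CPM in the others, 45.8 ± 36.6 at 1 h and 275 ± 113 at 2 h. Its call at 4 h was lost without untreated replicate 1 or 2 (edgeR adjusted p = 0.0513 and 0.0521). ENSMUST00000073707.8 (1596 nt) also had 0 counts in untreated cells, with 46.7 ± 57.2 CPM at 30 min, 93.7 ± 49.2 at 1 h, 104 ± 11 at 2 h and 237 ± 63 at 4 h, at least 902-fold higher than in untreated cells (edgeR adjusted p = 0.00918). It was called at 1 h and 2 h as well (edgeR adjusted p = 0.0374 and 0.0236), and the 4 h call held without any single library.

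Both falls ended at 0 counts at 4 h, which allows a mean of up to 0.405 CPM. ENSMUST00000162870.1 (1098 nt) had 40.3 ± 31.5 CPM in untreated cells, 41.3 ± 24.4 at 30 min, 25.9 ± 13.6 at 1 h and 6.28 ± 7.35 at 2 h, and was at least 99.3-fold lower at 4 h (edgeR adjusted p = 0.00412), a call that held without any single library. With the block it was called at 2 h too (edgeR adjusted p = 0.0233, against 0.197 without). ENSMUST00000212987.1 (6690 nt) went from 28.5 ± 6.1 CPM in untreated cells through 19.3 ± 7.4, 5.00 ± 5.03 and 5.58 ± 5.94 at 30 min, 1 h and 2 h, and was at least 70.3-fold lower at 4 h (edgeR adjusted p = 0.0349, and 0.0312 with the block). Its call was lost without untreated replicate 1, 2 or 3 (edgeR adjusted p = 0.0682, 0.0761 and 0.0738), without 4 h replicate 1, 2 or 3 (0.105, 0.0922 and 0.0746) and without 2 h replicate 1 (0.0506). Reads of isoforms that overlap these transcripts may have been assigned differently in different libraries, so that exact zeros describe the estimates and not the loci.

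**Figure D5:**
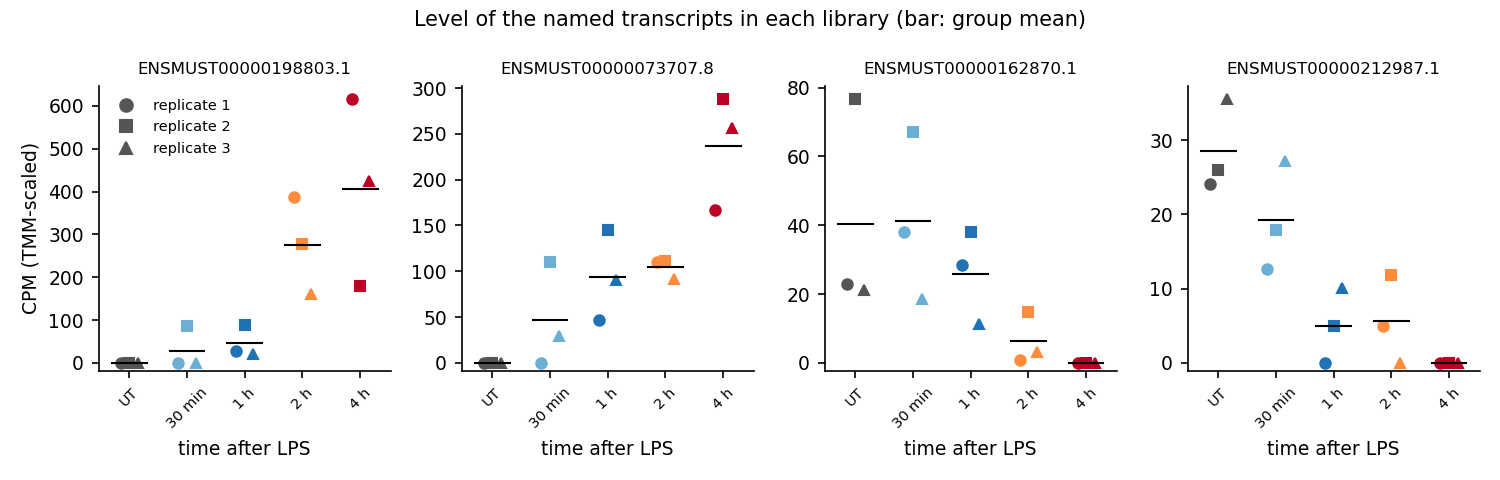
Level of the 4 named transcripts (y axis, CPM with TMM scaling, a separate linear scale for each) in each library by time after LPS (x axis; UT, untreated), with circles, squares and triangles for replicates 1, 2 and 3 and a bar for the mean. The first 2 rise from 0 to means of 406 and 237 CPM at 4 h, and the last 2 fall from means of 40.3 and 28.5 CPM to 0.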

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

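The tests of the 2 patterns weighed here were chosen after the patterns were seen, and the comparison with other groupings of the libraries was set before. The effect of LPS differed between times by a test of the difference itself in 2 comparisons: 195 transcripts differed between 1 h and 2 h and 24 between 2 h and 4 h. Between 30 min and 1 h edgeR called 0, with 2174 transcripts at an unadjusted p under 0.05 (4006 with the block), and DESeq2 222, so an absence of change between those times is not shown.

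For each comparison of 2 groups the 6 libraries allow only 10 splits, too few for a share under 0.05. The real split gave 170, 480, 1184 and 2884 calls against untreated cells at 30 min, 1 h, 2 h and 4 h, and the highest count of any other split was 1, 1, 0 and 1, so that 1 of 10 splits reached the real count each time. For 2 h against 1 h and 4 h against 2 h the real counts were 195 and 24 and the highest others 0 and 2, again 1 of 10. For 1 h against 30 min the real count was 0, which all 10 splits reached, the highest other giving 4. The replicate numbers pair the libraries, and among the 4 splits that part all 3 pairs, the real one included, the highest other count was 0 in every comparison. For the joint test of all times, 70 splits of the 15 libraries into 5 groups of 3 were compared, the real one included and the others drawn at random. Only 1 was as large as the real 2942, and the highest other gave 1. A random grouping is thus an unlikely origin of that count, but it is not excluded. These splits ignore the pairing by number, and groups that mix times can have a larger spread, which lowers their counts. Among 31 groupings that keep 1 library of each number in each group, the highest other count was 26.

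Libraries with the same replicate number deviated together, although the labels do not say what they share. Removing trends on transcript length and abundance from each library left the lowest same-number correlation at 0.213 (0.216 before), which argues against length bias. Among the 12509 transcripts with a mean of at least 100 counts it was 0.290, which decides nothing about counting noise, since noise that is independent between libraries can only weaken such correlations. Removing each transcript's trend with the share of the most abundant transcript took the lowest correlation to -0.265 and the median from 0.360 to 0.169, so a composition difference tied to that share may account for part of the pattern, though the share itself follows the numbers and its removal also removes what else does. It cannot be the only cause: 10 pairs with the same number lay on opposite sides of their groups in that share and should then correlate negatively, but the lowest of their correlations was 0.216 and the median 0.332. A preparation batch, a culture or an animal per number stays open, and no biological explanation was tested.

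Raised transcripts outnumbered lowered ones at 4 h with TMM (62.7% of calls) and were outnumbered with library size alone (25.4%). A candidate explanation is that the most abundant transcript distorts the library totals, but leaving it out and scaling by library size gave 26.6% raised, far from the TMM value, which argues against it. The called raised transcripts took 32.9% of the remaining counts at 4 h and 6.92% in untreated cells, but they were selected as raised from these libraries. Any growth of that kind lowers the share of all others. With library size and that transcript left out, the median log2 fold change of all tested transcripts was -0.779. Whether the growth accounts for that value was not tested. Whether the amount of chromatin-associated RNA per cell changed stays open, since no added standard RNA is described in the sources used here, and a general fall of most transcripts relative to a fixed amount was not tested.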

How the results depend on the processing

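Fits combining the block with other scalings or left-out libraries, and fits without the most abundant transcript, were chosen after seeing the data. Gene sums, gene lists, RNA classes by name and a protein-coding count were not run for want of gene names, and length offsets and a 200 nt filter were void. The replicate block raised the counts at 30 min, 1 h, 2 h and 4 h against untreated cells to 464, 1802, 4376 and 6992, between 1 h and 2 h to 1943, between 2 h and 4 h to 383 and at any time to 7510, the peaks to 352, 877, 953 and 2616 and the shared calls to 285 raised and 10 lowered. It changed no other call among the comparisons of 30 min with 1 h and the named transcripts at 4 h. With DESeq2 the 4 counts were 1122, 2491, 4335 and 6466, with 222 from 30 min to 1 h, 2373 from 1 h to 2 h, 827 from 2 h to 4 h and 8404 at any time. Library size alone gave 81, 241 and 566 at the first 3 times, 0 from 1 h to 2 h, peaks of 99 at 30 min and 532 at 4 h, and 54 raised and 1 lowered at both times. With only the 2 groups compared the counts were 0, 146, 422 and 1160, and 0 from 1 h to 2 h and from 2 h to 4 h. Without a filter they were 768 at 2 h, 27 from 1 h to 2 h and 8 from 2 h to 4 h. Limma on log2(TPM + 1) gave 959, 2134 and 5871 at 1 h, 2 h and 4 h, 353 from 1 h to 2 h and 78 from 2 h to 4 h, and on log2(TPM + 0.1) 4741 at 4 h and 120 from 2 h to 4 h. Leaving out the most abundant transcript gave 120 from 1 h to 2 h. With that and the block the counts were 454, 1785, 4282, 6879, 1873, 382 and 7449. The block with DESeq2 size factors gave 432, 1785, 4342, 6979, 1913, 370 and 7563, and with library size alone 1187, 3501 and 9010 at 1 h, 2 h and 4 h, 1096, 332 and 6970. The cause of these shifts was not tested, except that fits with fewer libraries have fewer degrees of freedom.

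Leaving out 1 library, or 1 replicate number of all groups, gave 0 to 381 at 30 min, 0 to 616 at 1 h, 0 to 1256 at 2 h, 69 to 2873 at 4 h, 0 to 5 from 30 min to 1 h, 0 to 214 from 1 h to 2 h, 0 to 22 from 2 h to 4 h and 0 to 2817 at any time. Against untreated cells, the lowest counts came from leaving out a whole replicate number, which left 2 libraries per group. Peak counts were then 0 to 6, 0 to 15, 0 to 10 and 0 to 136. With the block, leaving out 1 library gave 51 to 810, 320 to 2119, 1781 to 5068, 3950 to 6938, 0 to 2, 469 to 2347, 74 to 433 and 5052 to 7270 in the same order. Every count against untreated cells thus depended on single libraries, and the smaller ones were not stable. Other TMM-like scalings, a fold threshold of 2 and the stricter filter stayed within 1.5 times of the reported counts. The adjusted p of the named transcripts at 4 h ranged, over all alternatives, up to 0.142, 0.144, 0.0801 and 0.287, and every fold kept its direction. Most simulated changes were not called at any size simulated, up to 32-fold, at this number of libraries and the spreads simulated.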

Other observations

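The tests in this part were chosen after the results were seen. Transcripts called lowered were longer than those called raised: the median length was 3199.5 nt for the 1076 lowered at 4 h and 2443 nt for the 1808 raised, with 2088 nt over all tested transcripts, a difference that was not tested. Transcripts first raised at 30 min had a median of 2038 nt, against 2673 nt at 1 h, 2638 nt at 2 h and 2412 nt at 4 h.

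Longer and more abundant transcripts may be easier to call, which was not tested, and a set called early could differ in length for that reason alone. Tested transcripts were drawn 10000 times, matched on mean log2 CPM over all 15 libraries, LPS included. The median length was 3363 nt for draws matched to the 30 min set and 2877 nt for the 4 h set. Abundance measured in this way predicts longer transcripts at 30 min. The measured difference of the median log2 lengths of the 162 and 1005 transcripts was -0.24, outside the central 95% of the draws (0.06 to 0.40). The abundance matched on includes the rise itself, and the draws model neither the size of a change nor the calling. The draws thus do not decide whether detection caused the difference. The medians do not follow time, since the sets first raised at 1 h and 2 h were longer than the one at 4 h, and no biological explanation was tested. The lengths are those of spliced annotated transcripts and not of the transcribed loci, and several transcripts of one gene may be counted separately, which was not tested.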
